A study of Homo sapiens with 6 samples.

How the data were processed

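The samples are HEK293 cells, mock transfected or transfected with MOV10 siRNA, labelled with 700 µM 4-thiouridine for 60 min. Per the labels, total RNA was split on streptavidin beads after biotinylation of the label, and poly(A)+ TruSeq libraries of total, flow-through and labelled RNA were sequenced for 100 cycles. Per the labels' processing notes, reads were aligned with TopHat2 2.06 to hg18. The tool that made the expression values is not given in the sources used here. The deposited table holds a normalised expression signal per gene in 12 columns, whose unit the header does not name, and 4 half-life columns computed by the authors. Per the labels' protocols, the authors computed half-lives by a published method (Schwanhausser et al.). The other unit, that of the half-lives, is not named in the deposited header. It was settled as minutes by recomputing each half-life from the labelled, flow-through and total values, with first-order decay over 60 min and fraction weights fitted by total least squares. Pearson correlations of log2 deposited and log2 recomputed half-lives over genes were 0.971 and 0.962 in mock and 0.961 and 0.948 in siRNA, with recomputed medians of 708, 731, 692 and 655 min.

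GEO lists 6 samples, 1 per group, while the table gives replicates 1 and 2 of each group in its header. The plan made before the data were examined assumed 1 library per group and therefore held no test. All limma tests, the search for short sequences in 3' UTRs, the list percentiles of labelled RNA and all leave-one-out settings were added after the data were seen. All values in the table are 1.00 or more, so genes with a lower value in any column were left out before the table was made. The sum of the values per column is not a depth. In the 250 lowest genes of each group, ratios between the 2 columns were matched to ratios of whole numbers up to 60, after 1 factor per group. The tolerance was 1e-05 on the natural log scale. By the factor with the most matches, 46 to 81 genes matched. The mean over all factors tried was about 4.3, which is not the chance level of a best factor. The chosen factors are relative depths of replicate 2 over replicate 1: 1.20 and 1.01 in total mock and siRNA, 1.05 and 1.23 in labelled, and 1.20 and 1.32 in flow-through RNA. Between mock and siRNA only 15 or 16 genes matched, so depths of the conditions were not compared, and no counting interval is given. Spearman correlations between the 2 columns of a group lay between 0.993 and 0.996 over genes.

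Genes with a mean total RNA value of 5 or more in both conditions were kept, 6064 of 7682 (78.9%). The plan named this floor for the counts and named genes but not for the median half-life change, to which it was applied as well. Expression changes are differences of mean log2(value + 1), and half-life changes are differences of mean log2 half-life. Both were centred on the median gene in each column, except the medians of all genes, the folds of RNA levels and the values marked as uncentred. The size rule counts genes 1 log2 unit or more from the median gene. The limma model compared 2 siRNA with 2 mock columns, with moderated variances and a mean-variance trend, and p-values were adjusted by Benjamini-Hochberg over the 6064 genes at 0.05. Tested on simulated data with 2 columns against 2, it recovered 98.0% of changes of 1 log2 unit and 45.0% of changes of 0.5, and 7.14% of its calls were false.

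Named genes were chosen by a rule fixed before the data were examined. It takes MOV10 and UPF1, the 10 largest half-life increases and 10 largest decreases, the 5 largest total RNA increases and 5 largest decreases, and of each list the 2 largest half-life increases and 2 largest decreases. A gene had to pass the floor and not lie at the lowest or highest half-life of its column. For the half-life choices both siRNA columns had to lie on the same side of both mock columns, relative to the median gene; the total RNA choices did not ask for this. The rule asks for no test result. Gene lists, 29 in all, were fixed at the same time. A list with 5 or more members past the floor was compared with 10000 random lists of the same size matched on mean expression in 10 bins, and stood apart below percentile 2.5 or above 97.5. On simulated data 6.15% of unchanged lists stood apart, and a shift of 0.2 was found in 20 of 26 lists. Too small to test were snoRNA host genes (2 members), mitochondrially encoded genes (0) and markers of other cell types (3 past the floor). In the table, 10 symbols had been turned into dates and could not be matched to lists.

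Annotated 3' UTRs came from GENCODE v29, matched by symbol, taking the longest per gene of at least 20 bases (5663 of 6064 genes, 93.4%). No coordinates are given, because that annotation and the authors' alignment use different builds. For the search of 7-base sequences, half-life changes were fitted on log2 length and GC content of the 3' UTR, and each 7-base sequence present in at least 100 genes was scored by the mean residual of its genes and its z value. Tested on permuted changes with a planted effect of 0.15, the search ranked the planted sequence first in 20 of 20 rounds. Alternatives covered the pseudocount, the floor, the centring, recomputed half-lives, the size rule, the range of half-lives, the matching of random lists, the choice of 3' UTR, a replicate block and each column left out. With 1 column left in an arm, limma assumes that it varies like the others. Group comparisons by classes made by the authors were planned but not run, since the table used here holds no such classes. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.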

Results

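The series asked how the loss of MOV10, an RNA helicase, changed the stability of mRNAs in HEK293 cells, a human embryonic kidney line. Cells were transfected with MOV10 siRNA or mock transfected, and their new RNA was labelled with 700 µM 4-thiouridine (4sU) for 60 min. Poly(A)+ RNA was sequenced from 3 fractions: total RNA, 4sU-labelled RNA and the unlabelled flow-through. GEO lists 6 samples, 1 for each fraction and condition. The table used here gave 12 expression columns, 2 replicates for each of the 6 groups, and 4 half-life columns computed by the authors, for 7682 genes. Nothing in the sources used here says whether replicates 1 and 2 were separate cultures, so every p-value measures only the spread between these columns. The expression values were normalised by the authors, with no unit named, and none was below 1.00. They are not counts, so the depth of each library is unknown. Ratios of low values between the 2 columns of a group gave relative depths only, from 1.01 for replicate 2 over replicate 1 in total siRNA RNA to 1.32 in flow-through siRNA RNA. Comparisons were made on the 6064 genes with a mean total RNA value of 5 or more in both conditions. Expression changes are log2 differences after adding 1, and all log2 changes of genes and groups are given relative to the median gene unless stated otherwise. Folds of half-lives are relative to the median gene as well. Folds of RNA levels are plain ratios of group means, uncentred and without the added 1.

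Was MOV10 mRNA depleted, and did its partner in the study, UPF1, change? MOV10 total RNA was 13.8 ± 1.03 (SD, n = 2 columns) in mock and 3.59 ± 0.0828 (SD, n = 2 columns) after siRNA, a 3.86-fold lower level. Flow-through MOV10 RNA was 19.4 ± 0.238 (SD, n = 2 columns) in mock and 5.25 ± 0.174 (SD, n = 2 columns) after siRNA. In the labelled fraction, which holds RNA made within the labelling hour, MOV10 was at 3.07 ± 0.171 (SD, n = 2 columns) and 2.59 ± 0.0596 (SD, n = 2 columns). That is 1.19-fold lower before centring, and a log2 change of -0.32 relative to the median gene. The authors' half-lives of MOV10 mRNA were 2115 and 1985 min in the mock columns and 732 and 1012 min in the siRNA columns. MOV10 lay below the expression minimum after siRNA and was therefore not tested. UPF1, the central helicase of nonsense-mediated decay, had a total RNA value of 28.0 ± 3.91 (SD, n = 2 columns) in mock and 30.7 ± 0.156 (SD, n = 2 columns) after siRNA. Its half-life was 515 and 535 min in mock and 470 and 768 min after siRNA (change 0.00, limma, Benjamini-Hochberg adjusted p = 0.998).

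**Figure D1:**
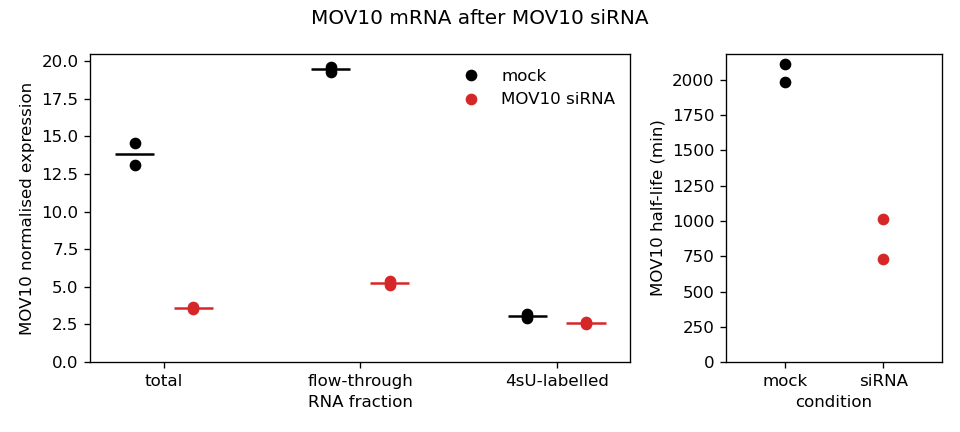
MOV10 mRNA in the 12 expression columns (left, the authors' normalised values, fraction on the horizontal axis) and in the 4 half-life columns (right, minutes). Points are replicate columns and lines are group means; total MOV10 RNA went from 13.8 to 3.59, and labelled MOV10 RNA from 3.07 to 2.59.

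Which mRNAs became less stable when MOV10 was depleted? Half-lives fell 2.35-fold to 3.45-fold in 9 named genes, in which both siRNA columns lay below both mock columns. The pseudogene transcript UBE2MP1 had half-lives of 888 and 1040 min in mock and 299 and 339 min after siRNA (3.45-fold shorter, log2 change -1.79, SE 0.11, limma, Benjamini-Hochberg adjusted p = 0.0036). UBE2MP1 resembles its parent gene UBE2M in sequence, and reads shared by the pair were not separated here. The CDC42 effector CDC42EP1 went from 268 and 269 min to 83 and 142 min (2.82-fold shorter). MBNL1, a regulator of alternative splicing, went from 1009 and 973 min to 383 and 438 min (2.77-fold shorter). The mitochondrial glycerol-3-phosphate dehydrogenase GPD2 went from 1113 and 1144 min to 456 and 497 min, and the ubiquitin ligase RNF6 from 261 and 244 min to 92 and 136 min. The splicing factor WBP11 and the ribosome subunit anti-association factor EIF6 were each 2.53-fold shorter. FAM171A1 and the tetraspanin TSPAN14 were 2.37-fold and 2.35-fold shorter, TSPAN14 with a log2 change of -1.23, against -0.68 in half-lives recomputed from the expression values. The forkhead transcription factor FOXP2 had the next largest drop after UBE2MP1 in size (-1.56, SE 0.44) but did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.085). Its mock half-lives were 935 and 392 min, against 154 and 357 min. Of these 10 genes, 9 had an annotated 3' UTR, and 7 of them carried the 7-base sequence TACTGCA in it (MBNL1, GPD2, RNF6, WBP11, EIF6, FAM171A1 and TSPAN14).

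Most genes with shorter half-lives were also lower in total RNA, but half-lives are computed from the same expression values, so the counts are not independent and no value expected without change was computed. Across the 6064 genes, 259 half-lives fell and 114 rose (limma, Benjamini-Hochberg adjusted p under 0.05), and 1475 genes passed an unadjusted 0.05. Of the 259, total RNA fell in 222 and labelled RNA in 66, with median changes of -0.60 and -0.08. By the size rule fixed before the data were examined, 30 genes were shorter and 2, ADAT2 and ADARB1, were longer by 1 log2 unit or more. Total RNA was lower by the same limma test in 28 of the 30. The test counts fell whichever column was left out, which also leaves fewer columns to measure the spread. By the size rule, 33 to 42 genes were shorter and 1 to 5 longer with 1 column left out.

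Which mRNAs became more stable? E2F5, a member of the E2F family of cell cycle transcription factors, went from 399 and 432 min in mock to 859 and 894 min after siRNA (1.85-fold longer, log2 change 0.88, SE 0.13, limma, Benjamini-Hochberg adjusted p = 0.0168). Its total RNA rose from 11.4 ± 1.46 to 18.9 ± 0.672 (SD, n = 2 columns). LYRM5 went from 1047 and 980 min to 2391 and 2046 min, and its adjusted p lay close to the threshold (limma, Benjamini-Hochberg adjusted p = 0.0497). The transmembrane protein genes TMEM64, TMEM9B and TMEM136 rose 1.76-fold, 1.72-fold and 1.69-fold in half-life. RHEBL1, a small GTPase gene, rose 1.74-fold, and PKIB, an inhibitor of protein kinase A, 1.70-fold. The total RNA of RHEBL1, PKIB and TMEM136 did not pass the test (-0.10, -0.02 and 0.06). In recomputed half-lives the log2 change was 0.25 for RHEBL1 (0.80 in those of the authors), 0.51 for PKIB (0.77) and 1.23 for TMEM64 (0.81). The other 3 named genes, ADAT2, ADARB1 and GLI4, did not pass in half-life. Labelled RNA fell by the same test in 7 of the 10, LYRM5, TMEM64, TMEM9B, PKIB, TMEM136, GLI4 and ADAT2, with log2 changes of -0.62, -0.50, -0.27, -0.42, -0.61, -0.68 and -0.57. ADAT2, a subunit of a tRNA adenosine deaminase, was at 94 and 109 min in mock and 837 and 152 min after siRNA (limma, Benjamini-Hochberg adjusted p = 0.258). The RNA-editing enzyme ADARB1 was at 1132 and 1061 min against 1669 and 3876 min (1.02, and 0.40 recomputed), and GLI4 at 333 and 259 min against 415 and 965 min. Of these 10 genes 9 had an annotated 3' UTR, and 2 of them, ADAT2 and ADARB1, carried TACTGCA. Of the 114 genes with longer half-lives by the test, total RNA rose in 76 and labelled RNA fell in 28, with median changes of 0.33 and -0.14. These counts, and that of the 7 named genes, are not independent of the choice of genes, as half-lives are computed from the same expression values.

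**Figure D2:**
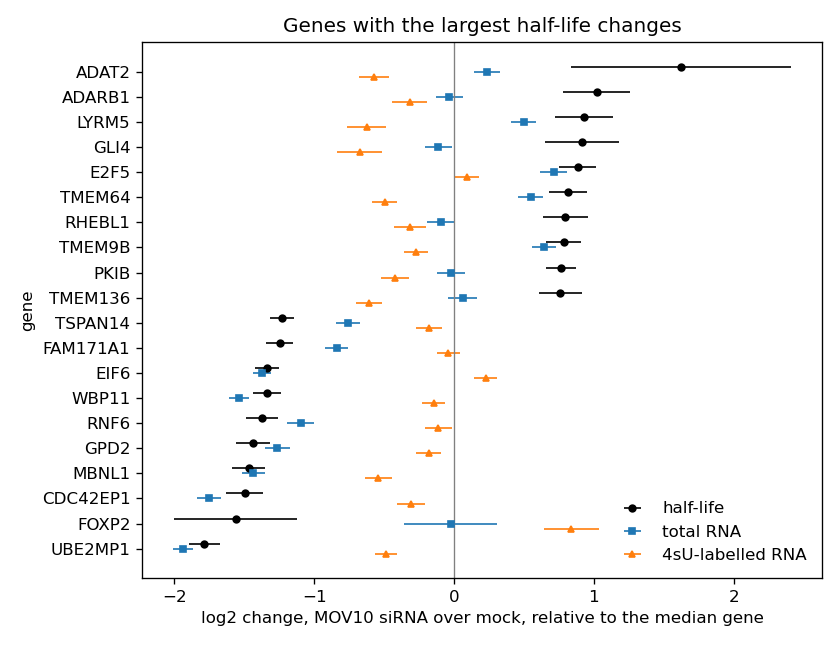
The 20 genes with the largest half-life changes that went the same way in both replicates, with their changes in half-life, total RNA and 4sU-labelled RNA (log2, MOV10 siRNA over mock, relative to the median gene). Points are differences of the means of 2 columns and bars are limma standard errors; UBE2MP1 is at -1.79 and ADAT2, with the widest bar, at 1.62 in half-life.

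Did half-lives shift as a whole? The median half-life of the 6064 genes was 742 and 810 min in the mock columns and 764 and 1030 min in the siRNA columns. The median log2 change of all genes was 0.20 before centring. It was 0.04 between the columns of replicate 1 and 0.36 between those of replicate 2, while the siRNA columns differed from each other by 0.43 and the mock columns by 0.12. Half-lives recomputed from the expression values with 1 rule for all columns gave a median change of -0.11, the opposite sign. Between conditions, gene half-lives ranked closely alike across genes, which are not independent replicates (Spearman 0.970, Pearson 0.975). Between the 2 columns of mock and of siRNA the Spearman values were 0.983 and 0.981. The SD of the relative changes over genes was 0.26, against 0.14 from the spread between columns. In 55.8% of genes the mock and siRNA columns did not overlap, where chance gives 33.3% if all columns are independent, which is not known. All genes share the same columns.

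Which mRNAs changed in abundance? ZCCHC12, a zinc finger gene, had the largest drop in total RNA, from 48.1 ± 3.58 to 8.19 ± 0.201 (SD, n = 2 columns), 5.86-fold lower (log2 change -2.39, limma, Benjamini-Hochberg adjusted p = 3e-10). Its labelled RNA fell by 1.69, more than its half-life, which fell by 0.56 on the log2 scale. UBE2MP1 total RNA went from 141 ± 12.1 to 35.6 ± 3.27 and CDC42EP1 from 63.1 ± 10.3 to 17.7 ± 1.27 (SD, n = 2 columns). WBP11 was 3.06-fold and MBNL1 2.99-fold lower. TSPAN12, a tetraspanin of the Norrin receptor complex, rose 2.00-fold from 9.98 ± 0.271 (SD, n = 2 columns) in mock, a change of 0.95 (limma, Benjamini-Hochberg adjusted p = 7.5e-06). The nucleotide kinase gene CMPK1 rose 1.86-fold, FAM135A 1.83-fold and PHTF2 1.80-fold. UTP14C, a retrocopy of UTP14A, was named by the rule at 0.79 but did not pass (limma, Benjamini-Hochberg adjusted p = 0.130). The choice by total RNA asked for no agreement between columns, and UTP14C was at 16.3 and 64.2 in mock and 65.9 and 48.0 after siRNA. In total RNA 783 genes rose and 868 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and 34 were lower and 0 higher by 1 log2 unit or more. Without siRNA replicate 1 the test gave 322 and 534, without siRNA replicate 2 it gave 402 and 611, and without mock replicate 2 it gave 490 and 643.

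Labelled RNA, which follows synthesis and decay within the labelling hour, changed in fewer genes than flow-through RNA. In the labelled fraction 599 genes rose and 700 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and without mock replicate 2 the counts were 379 and 447. In flow-through RNA 1925 rose and 1626 fell. By 1 log2 unit or more, 9 genes were lower and 0 higher in labelled RNA, against 90 lower and 1 higher, ADAT2, in flow-through RNA. ADAT2 rests on 1 column, with flow-through values of 8.13 and 8.40 in mock and 51.2 and 7.67 after siRNA. ZCCHC12, UBE2MP1 and MBNL1 fell in both fractions, with labelled changes of -1.69, -0.49 and -0.54. Before centring, the median change was -0.01 in total, 0.14 in labelled and 0.02 in flow-through RNA. The difference in number of genes between the fractions was not tested.

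Did groups of genes change stability together? Of 29 gene lists fixed before the data were examined, 26 had at least 5 members to test, and 6 stood outside random lists matched on expression. By chance 1.3 would, if the genes of a list varied independently of each other, which was not tested. Without mock replicate 1, 2 lists stood apart. Histone genes had the lowest median change (-0.21, percentile 0.01 of 10000 random lists). The libraries were poly(A)+, so these values cover polyadenylated histone transcripts only. Of the 22 histone genes 0 passed limma, adjusted over all genes or adjusted over the list alone, and 2 passed an unadjusted 0.05. HIST1H2BK was at 320 and 290 min in mock and 227 and 255 min after siRNA, and H2AFX at 142 and 126 min against 107 and 151 min. H1F0 was at 310 and 350 min against 359 and 535 min. The histone list no longer stood apart without siRNA replicate 2 (median -0.03), in half-lives recomputed from the expression values (-0.10, percentile 16.9), or among genes between the 5th and 95th percentile of half-life, where the median turned to 0.07. Mitochondrial ribosomal protein genes had a median of -0.05 (percentile 2.10). Of these 57 genes 2 fell, both also when adjusted over the list alone (2). MRPS2 went from 207 and 201 min to 91 and 131 min and MRPL3 from 754 and 811 min to 527 and 646 min. The mitochondrial list no longer stood apart without mock replicate 1 (percentile 4.03), mock replicate 2 (4.79) or siRNA replicate 2 (7.66). The same held against random lists matched on half-life (7.70), by the mean of the list (7.85), with an expression minimum of 20 (3.37) and between the 5th and 95th percentile of half-life (2.97).

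Targets of the let-7 microRNA family had a median change of 0.14 (percentile 99.2). Of 22 genes, 3 half-lives rose and 3 fell over all genes, and 10 passed when adjusted over the list alone. E2F5 and the cyclin gene CCND1 rose, the latter from 194 and 241 min to 316 and 447 min. HMGA2, a chromatin protein gene, fell from 895 and 853 min to 481 and 657 min, and the microRNA processing enzyme DICER1 from 396 and 409 min to 301 and 387 min. The remaining 2, RRM2 (higher) and HRAS (lower), were named after their values were seen. In recomputed half-lives HMGA2 was at -0.44 (-0.83 in those of the authors), DICER1 at -0.18 (-0.43) and RRM2 at 0.64 (0.39). Genes of deadenylation, decapping and 5'-to-3' decay had a median of 0.10 (percentile 98.5), with 0 of 29 past limma over all genes, 6 adjusted over the list alone and 10 by an unadjusted 0.05. The decapping enzyme DCP2 was at 529 and 604 min in mock and 806 and 940 min after siRNA, and the antiproliferative gene BTG2 at 49 and 50 min against 66 and 108 min. EDC3, an enhancer of decapping, was at 497 and 586 min against 425 and 563 min. Without mock replicate 1 the let-7 list no longer stood apart (percentile 97.3), nor without mock replicate 2 (95.3), and with an expression minimum of 20 its median turned to -0.0050. The decay list no longer stood apart without mock replicate 2 (97.3), with a minimum of 20 (74.0), in recomputed half-lives (97.2), between the 5th and 95th percentile of half-life (96.3), without genes shared with other lists (96.7) or without genes that carry TACTGCA (95.1).

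Cytosolic ribosomal protein genes had a median of 0.08 (percentile 99.1), with 38 of 50 genes above the median gene and 0 past limma, over all genes or adjusted over the list alone (3 by an unadjusted 0.05). RPL39 was at 1095 and 1237 min in mock and 1367 and 1915 min after siRNA, and RPL13 at 1689 and 1569 min against 1236 and 1849 min. In recomputed half-lives the ribosomal median turned to -0.14. Zinc finger genes of the ZNF series had a median of 0.05 (percentile 99.1). Of 201 ZNF genes 2 rose and 3 fell, and 1 passed when adjusted over the list alone. ZNF345 rose from 229 and 244 min to 349 and 445 min, and ZNF238 fell from 204 and 205 min to 114 and 156 min. ZNF283 also rose, and ZNF414 and ZNF205 fell, named after their values were seen. In recomputed half-lives ZNF345 was at 0.22 (0.54 in those of the authors), ZNF238 at -0.41 (-0.82), ZNF414 at -0.17 (-0.45) and ZNF205 at -0.09 (-0.43). The ZNF median turned to -0.04 in recomputed half-lives, where the list stood apart in the opposite direction (percentile 2.03), and to -0.0022 without siRNA replicate 1. Ribosomal protein genes have many processed pseudogenes, and reads shared with them were not separated here. The ribosomal list no longer stood apart without mock replicate 1 (percentile 91.3) or siRNA replicate 2 (85.2), and the ZNF list without mock replicate 1 (89.7). With an expression minimum of 20 the ribosomal list was at 97.4 and the ZNF list at 59.9, and by the mean of the list they were at 96.4 and 95.1, all inside the limits. So were the ribosomal list against random lists matched on half-life (96.4) and the ZNF list without genes that carry TACTGCA (92.3).

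**Figure D3:**
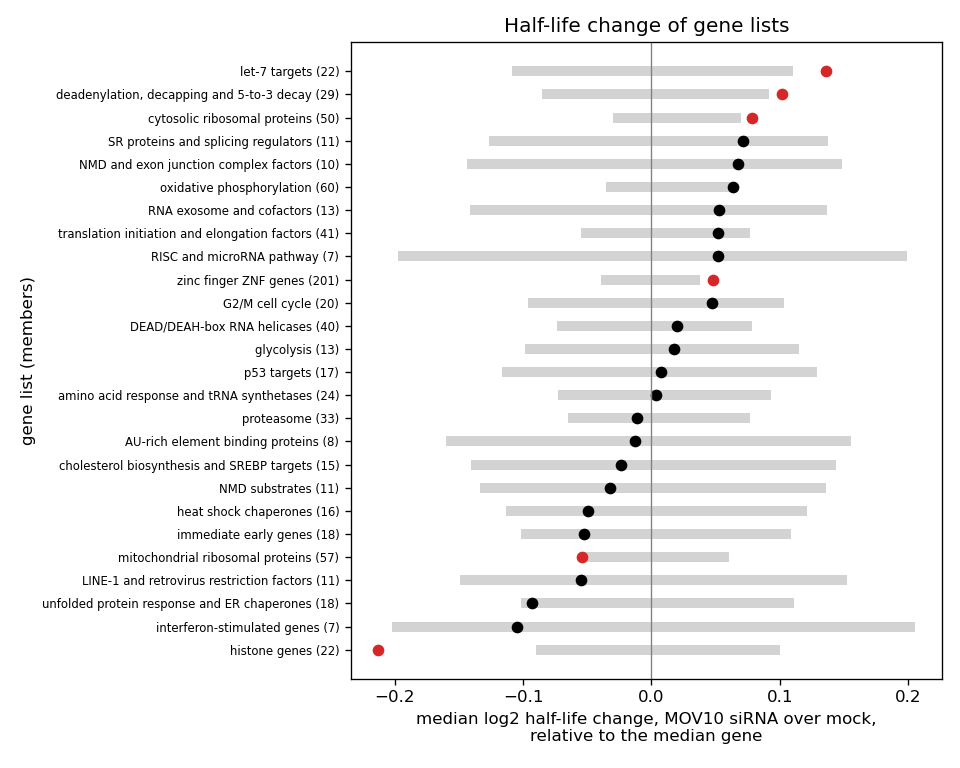
Median half-life change of the 26 gene lists (log2, MOV10 siRNA over mock, relative to the median gene), with the number of members in brackets. Points are list medians, grey bars show where random lists of the same size and expression lay between the lower and upper percentile limits, and red points fall outside; histone genes are lowest at -0.21 and let-7 targets highest at 0.14.

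Known targets of nonsense-mediated decay did not stand apart. Their median change was -0.03 (percentile 27.4), with 0 of 11 past limma, over all genes or adjusted over the list alone, and 1 by an unadjusted 0.05. PPP1R15A, a stress-response phosphatase subunit, was at 110 and 126 min in mock and 82 and 123 min after siRNA. GADD45B was at 79 and 76 min against 66 and 91 min, and the decay kinase SMG1 at 1165 and 1143 min against 1242 and 1717 min. In recomputed half-lives the median of these targets was -0.35 and lay below the lower limit (percentile 0.18). Factors of nonsense-mediated decay and the exon junction complex had a median of 0.07, with 0 of 10 past the test (2 by an unadjusted p). The RISC and microRNA pathway list had a median of 0.05, and 1 of its 7 genes fell, DICER1. RNA exosome genes were at 0.05 and DEAD/DEAH-box helicases at 0.02, with 0 of 13 and 0 of 40 past the test (2 and 5 by an unadjusted p). In recomputed half-lives the helicase median turned to -0.15 (percentile 0.98). SR proteins and splicing regulators were at 0.07, with 0 of 11 past it (2 by an unadjusted p). AU-rich element binding proteins were at -0.01, and 1 of 8 fell, ZFP36L2, an mRNA decay factor, from 100 and 100 min to 61 and 92 min. Its change turned from -0.62 to 0.68 in recomputed half-lives. With no expression minimum the AU-rich list stood apart (-0.15, percentile 1.37). LINE-1 and retrovirus restriction factors, a group to which MOV10 itself is often assigned, were at -0.06, with 0 of 11 past the test (2 by an unadjusted p).

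In metabolic, stress and cell cycle lists the medians of the authors' half-lives did not stand apart from lists matched on expression. Glycolysis genes had a median of 0.02, and 1 of 13 fell: lactate dehydrogenase LDHA, from 1300 and 1486 min to 578 and 806 min. LDHA carried the sequence TACTGCA in its 3' UTR, as did CENPF and EIF6 of the genes that fell in the lists below. NDUFB10, CANX, PDIA6, JUN and EIF5 did not, though PDIA6 and JUN carried the overlapping sequence ACTGCAA and CANX the 6-base ACTGCA. Oxidative phosphorylation genes were at 0.06, and 1 of 60 fell, the complex I subunit NDUFB10, from 1426 and 1649 min to 821 and 1115 min. Unfolded protein response and ER chaperone genes were at -0.09, with 3 of 18 lower over all genes and 4 past the test adjusted over the list alone. Calnexin, CANX, fell from 1695 and 1910 min to 1119 and 1562 min, and the disulfide isomerase PDIA6 from 1178 and 1311 min to 943 and 1210 min; EDEM1 was the other. Cholesterol genes were at -0.02, and 1 of 15 rose, the sterol sensor partner INSIG1, from 336 and 367 min to 525 and 618 min. The amino acid response list was at 0.00, and 1 of 24 rose, VLDLR, from 307 and 387 min to 500 and 743 min. Immediate early genes were at -0.05, but at 0.33 in recomputed half-lives, above all random lists. Of 18, the transcription factor JUN fell from 98 and 90 min to 54 and 84 min, and the survival factor MCL1 rose from 138 and 148 min to 197 and 256 min. Several members moved by over 1.5 times in recomputed half-lives: JUN was at -0.08 (-0.67 in those of the authors), MCL1 at 0.80 (0.46), INSIG1 at 0.94 (0.50), VLDLR at 0.31 (0.63), EDEM1 at -0.14 (-0.39) and EIF5 at -0.24 (-0.39). G2/M genes were at 0.05, and 1 of 20 fell, the kinetochore gene CENPF, from 665 and 731 min to 378 and 385 min. Translation factors were at 0.05, and 2 of 41 fell, EIF6 and EIF5. Heat shock chaperones were at -0.05, with 1 of 16 lower, the cochaperone BAG3. BAG3 and EDEM1 were named after their values were seen. The proteasome was at -0.01, p53 targets at 0.01 and interferon-stimulated genes at -0.10, with 0 of 33, 0 of 17 and 0 of 7 past the test over all genes (6, 8 and 1 by an unadjusted p). Adjusted over the list alone, 3 genes each passed among immediate early, cholesterol and p53 genes, 4 among translation factors, and 2 each among heat shock and AU-rich element binding genes. Leaving out mock replicate 2 set apart immediate early genes (percentile 1.32), oxidative phosphorylation (98.6) and the unfolded protein response (2.27). The unfolded protein response also stood apart without siRNA replicate 2 (0.29), and the proteasome without siRNA replicate 1 (0.42). In recomputed half-lives the proteasome (-0.24, percentile 0.02), heat shock chaperones (-0.28, 0.22) and the unfolded protein response (-0.21, 1.02) stood apart. The unfolded protein response did so as well between the 5th and 95th percentile of half-life (0.44), by the mean of the list (1.06) and without genes that carry TACTGCA (0.28). Oxidative phosphorylation stood apart with an expression minimum of 20 and without the genes at the ends of a column's half-lives (97.8).

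Did the same lists change in total RNA? Of the 26, 10 stood apart. Immediate early genes had the lowest median (-0.29, below all random lists), and 10 of 18 fell, among them JUN, from 91.0 ± 8.72 to 59.2 ± 0.348 (SD, n = 2 columns). In labelled RNA 14 of the 18 fell. Unfolded protein response genes (-0.15) and mitochondrial ribosomal proteins (-0.07) were also lower, with 6 of 18 and 10 of 57 genes past the test in that direction. CANX fell from 219 ± 19.8 to 135 ± 5.0 (SD, n = 2 columns). G2/M genes had a median of 0.17, and 6 of 20 rose while 2 fell. The mitotic kinesin KIF11 rose by 0.40 and CENPF fell by 0.68. Targets of let-7 had a median of 0.16, and 9 of 22 rose while 2 fell, HMGA2 among them, from 21.4 ± 0.860 to 8.83 ± 0.410 (SD, n = 2 columns). Factors of nonsense-mediated decay had a median of 0.16, decay factors 0.10, amino acid response genes 0.09, ZNF genes 0.06 and translation factors 0.06. SMG1, which is also a listed target of nonsense-mediated decay, rose from 18.7 ± 0.371 to 26.0 ± 0.311 (SD, n = 2 columns). Leaving out 1 column or another ended the call of the decay factor, nonsense-mediated decay factor, ZNF, translation factor and mitochondrial ribosomal lists. So did unmatched random lists for amino acid response genes (percentile 96.3) and translation factors (90.9), and no expression minimum for translation factors (95.3). The number of lists apart was 6 without siRNA replicate 2.

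How stable were these groups in mock cells? Immediate early genes had the shortest median half-life of the lists, 54.1 min. Histone genes followed at 161 min (polyadenylated transcripts only, as the libraries were poly(A)+) and ZNF genes at 262 min. Targets of nonsense-mediated decay were at 333 min, p53 targets at 350 min, let-7 targets at 485 min and mitochondrial ribosomal proteins at 564 min. These 7 lists lay below random lists. The proteasome at 1198 min, oxidative phosphorylation at 1307 min, cytosolic ribosomal proteins at 1336 min and glycolysis at 1607 min lay above them. The same number of lists, 11, stood apart when either mock column was left out.

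The series title names movement of MOV10 along 3' UTRs, so half-life changes were also compared across 3' UTR lengths. Medians in 5 bins from the shortest to the longest annotated 3' UTR were -0.03, -0.01, 0.01, 0.02 and 0.02, over 5663 genes. The longest bin exceeded the shortest by 0.06, against -0.02 to 0.02 in 2000 random gene orders. Those orders treat genes as independent and do not measure the spread between columns, so they do not show a change between conditions. Total RNA showed the same order of bins, from -0.05 in the shortest to 0.07 in the longest, and labelled RNA the opposite one, from 0.05 to -0.02. Recomputed half-lives gave a wider difference of 0.21. In the authors' half-lives the difference was 0.06 without mock replicate 1 and 0.03 without mock replicate 2. In 5 bins of mean half-life, genes with the shortest half-lives had a median change of -0.06 and those with the longest 0.03. In recomputed half-lives these medians were 0.01 and -0.02.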

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

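All limma settings, leave-one-out settings, the setting without genes that carry TACTGCA and the recomputed 3' UTR contrast were chosen after seeing the data. Of the values that answer a comparison, 152 alternatives moved by less than the spread between replicates (for counts, by at most 1.5 times) and 71 by more. That spread is wide for the median half-life change, where even a change of sign lay within it. For single lists, 553 kept their direction and side of the limit, 55 lay inside it with the other direction, 40 fell inside it, 17 passed it and 7 reversed. Where a value moved, the cause was not tested unless the setting itself gives it, as fewer or more genes under another floor do. Depth is unknown, so the precision of low values cannot be bounded.

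With no floor, 7 genes were longer and 48 shorter by 1 log2 unit in half-life, 1 was higher in total RNA, 6 were higher and 20 lower in labelled RNA, and 5 higher in flow-through RNA. With a floor of 20, 0 were longer and 10 shorter, 2 lists stood apart in half-life, and the median of let-7 targets reversed to -0.0050. A threshold of 0.5 gave 101 longer and 240 shorter, and no centring gave 6 and 12. Restricting genes to the 5th to 95th percentile of half-life gave 0 longer, a Spearman correlation of 0.957 and a histone median of 0.071, reversed. Recomputed half-lives gave a median change of -0.11, 35 longer genes, a correlation of 0.951, a 3' UTR contrast of 0.21, and reversed medians for ZNF genes (-0.045), cytosolic ribosomal proteins (-0.14), immediate early genes (0.33) and DEAD/DEAH-box helicases (-0.15). Without genes that carry TACTGCA, 0 were longer and 14 shorter.

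A pseudocount of 0.1 gave 1 higher gene in total RNA and 1 higher and 14 lower in labelled RNA; a pseudocount of 5 gave 12 lower in total, 4 lower in labelled and 43 lower in flow-through RNA. The uncentred MOV10 change was -1.69 in total, -0.18 in labelled and -1.71 in flow-through RNA with a pseudocount of 1, and -1.95, -0.25 and -1.89 without one; relative to the median gene it was -0.32 in labelled RNA with a pseudocount of 1. Trimmed-mean rescaling set the labelled median to 0.00023, as its construction does. The contrast between 3' UTR bins was 0.046 with the median annotated 3' UTR, and bins of total RNA in place of half-life gave 0.0085. By construction, 1 entry per symbol (no symbol repeats) and trimmed-mean rescaling of centred counts moved nothing. Classes made by the authors were not run.

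The numbers 1 and 2 are not shown to pair mock with siRNA columns: replicate deviations correlated at -0.07 over genes in half-life and 0.05 in total RNA. With a replicate block, limma gave 21 longer and 118 shorter half-lives, 1124 higher and 1123 lower genes in total, 732 and 823 in labelled and 2003 and 1701 in flow-through RNA. The ratio of flow-through to labelled values in place of half-lives gave 181 higher and 296 lower, and no floor gave 80 and 221.

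Leaving out each column in turn gave these ranges. The median half-life change ran from -0.02 to 0.42, genes longer from 1 to 5 and shorter from 33 to 42, and the correlation from 0.961 to 0.969. In total RNA 1 to 3 genes were higher and 35 to 36 lower, in labelled RNA 0 to 6 and 6 to 15, and in flow-through RNA 0 to 3 and 81 to 103. The uncentred MOV10 change ran from -1.76 to -1.62 in total, from -0.22 to -0.14 in labelled and from -1.74 to -1.68 in flow-through RNA. Its uncentred half-life change ran from -1.48 to -1.02, and with all columns it was -1.25, or -1.45 relative to the median gene. Lists apart numbered 2 to 6 in half-life and 6 to 9 in total RNA, and the ZNF median ran from -0.0022, reversed, without siRNA replicate 1 to 0.078 without siRNA replicate 2. The 3' UTR contrast ran from 0.032 to 0.060 and that of half-life bins from 0.07 to 0.09. By limma, longer half-lives ran from 1 to 75 and shorter from 48 to 173, total RNA from 322 to 834 higher and 534 to 931 lower, labelled RNA from 379 to 498 and 447 to 647, and flow-through RNA from 1301 to 1652 and 1301 to 1479.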

Other observations

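All tests in this part were chosen only after the results they examine were seen, including the search for short sequences, the microRNA family sites and the comparison of the siRNA columns. Some gene groups too small or too varied for a comparison still had clear members. SYP, the synaptic vesicle gene on the list of markers of other cell types, rose in total RNA from 21.5 ± 1.07 to 32.2 ± 1.89 (SD, n = 2 columns; limma, Benjamini-Hochberg adjusted p = 7.2e-05), with half-lives of 1262 and 1449 min in mock and 1470 and 2356 min after siRNA. The haemoglobin genes HBA1 and HBA2, which share most of their sequence, were at 16.5 and 14.6 in mock and 18.8 and 15.8 after siRNA. Of snoRNA host genes, SNHG11 was at 21.7 and 20.6 and CCAR1 at 31.8 and 29.8. In labelled RNA 12 of 26 lists stood outside random lists matched on expression. G2/M genes had a median of 0.23 with 8 of 20 higher by limma, cytosolic ribosomal proteins 0.15 with 10 of 50, the proteasome 0.13 with 8 of 33, and DEAD/DEAH-box helicases 0.12 with 9 of 40. Mitochondrial ribosomal proteins were at 0.12 and ZNF genes at 0.09, with 9 of 57 and 29 of 201 higher and 5 and 17 lower. The 5, named after their values were seen, were MRPL4, MRPL38, MRPL42, MRPS10 and MRPS36. Targets (0.21) and factors (0.17) of nonsense-mediated decay, heat shock chaperones (0.16), decay factors (-0.09) and oxidative phosphorylation (-0.04) were the others, beside immediate early genes at -0.39, with 14 of 18 lower. INSIG1 fell by 1.04.

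A short sequence was more frequent in the 3' UTRs of genes with shorter half-lives, though most of those called by limma lacked it. Of the 251 called genes with a 3' UTR, 97 (38.6%) carried TACTGCA and 154 did not. Random lists matched on 3' UTR length had a median of 12.4%. Among the 102 genes with longer half-lives by limma, 4 carried it (3.92%, random median 13.7%). Of 13991 7-base sequences in the 3' UTRs of 5663 genes, TACTGCA had the lowest z value for half-life change (-14.1, against a lowest value of -5.10 in 100 permutations of the changes over genes). Its 662 genes had a mean residual of -0.14. It also led for total RNA (z -15.6) and flow-through RNA (-12.4), and not for labelled RNA. Genes with the 8-base form TACTGCAA (176) had a median half-life change of -0.14, and those with TACTGCA alone (486) -0.05. Genes with neither these nor the related forms ACTGCAA and ACTGCA (3175) were at 0.01. Among genes with no such site in the 3' UTR, 88 with the 8-base form in the coding sequence had a median of -0.12. The sequence was again first without the 30 genes shorter by 1 log2 unit (z -12.5), and when found in one random part of the genes it had z -10.7 in the other. The MOV10 transcript of 3641 bases holds 2 copies, where its length alone gives 0.222.

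For the genes with a half-life shorter by 1 log2 unit or more, the median change was -0.97 in half-lives recomputed with 1 rule. The drop was thus present in the expression values without the authors' scaling of the fractions. This decides nothing on that scaling as a cause. Both half-lives use the same expression values, and centring on the median gene removes most of a factor shared by a column. A candidate explanation is siRNA seed matches in the 3' UTR: 58.6% of the 29 genes with a 3' UTR carried TACTGCA, against a median of 10.3% and an upper limit of 24.1% in random lists matched on 3' UTR length. The siRNA sequence is not given in the sources used here, so the match itself was not checked, and the sequence was found from these data. Of the other 12 genes, 4 carried the 7-base form ACTGCAA (DLX2, PGRMC2, CCNJ and FOXP2) and 3 only the 6-base ACTGCA (LAPTM4A, SNX12 and BTBD1). The other 5 carried none of these (MRPS2, CDC42EP1, GMPPA, CALM3 and GPATCH8). Over all 5663 genes, 710 carried ACTGCAA without TACTGCA and 1116 only ACTGCA, with median half-life changes of 0.00 and -0.01. These forms are therefore common, and the medians of both classes, not adjusted for 3' UTR length, lay near the 0.01 of genes with no site. Of their genes, 49.7% and 52.7% were shorter than the median gene, against 46.5% with no site. In the search, adjusted for length and GC content, ACTGCAA had a z of -9.66 over 1034 genes, some of which also carry TACTGCA. Whether these forms mark shorter half-lives on their own was therefore not settled. Loss of MOV10 protein stays open, since with 1 siRNA every siRNA column holds both the siRNA and the loss of MOV10, and these cannot be told apart.

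The microRNA-17 family site GCACTTT had the highest z value of all 7-base sequences for half-life (3.32, 1369 genes), and 75 of 100 permutations gave a z as high for some sequence. It also had the highest z for total RNA (4.07, reached in 10 of 100) and flow-through RNA (4.42, reached in 1). In labelled RNA its z was 2.64, reached for some sequence in 100 of 100. Sites of 14 families were listed after the scan was seen, so their counts are not independent of it. Among them, 1 of 100 permutations reached the z of GCACTTT for half-life, 1 for labelled RNA, and 0 for total or flow-through RNA. The mean half-life difference was 0.054, 0.030 (SE 0.0083) after removal of 3' UTR length and GC content, and 0.030 (SE 0.0084) when genes with a TACTGCA site were also left out. The mean did not fall when the genes with a TACTGCA site were left out, so the difference did not rest on those genes. That does not set the difference apart from chance, since GCACTTT was picked by its z. For the same reason these values decide nothing on 3' UTR length and GC content, which stay open. Release of microRNA targets stays open as well: the largest mean half-life change of any sequence, 0.061 for TGACGAT, was reached in 94 of 100 permutations, which does not bound the smaller mean of 0.022 for GCACTTT.

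Half-lives were longer in the second siRNA column by over 0.4 log2 units. The authors' scaling of the fractions is a candidate explanation, as the gap was -0.072 in half-lives recomputed with 1 rule for all columns, where the deposited values gave 0.43. Less labelled RNA in that library cannot be told apart from it: the ratio of labelled to flow-through values differed by -0.0027 between the columns, but their sums differ by 2.40% and 1.80%, so the values are scaled per library and do not show a lower yield. No biological explanation was tested, since both columns come from the same group.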
